A study of Mus musculus with 9 samples.

How the data were processed

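The data are a mouse Illumina bead array series of 9 arrays: 3 of ES cells, 3 of definitive endoderm (DE) and 3 of anterior foregut cells (AFE) made in culture. Cells were sorted by flow cytometry, per the series description in the labels, and the gate of each sample is not given in the sources used here. Per the labels, AFE cells are of the 129X1/SvJ strain, DE cells of a 129X1/SvJ x 129S1 cross and ES cells without reporter of 129P2/OlaHsd. Per the labels, cells were grown on mouse embryonic fibroblasts with LIF and depleted of them before differentiation. Per the labels, 500 ng of total RNA were amplified and labelled. The scanner software is not given in the sources used here. The day of collection is not stated in the labels.

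The deposited intensity values are summarised bead signals per probe on a linear scale without normalization between arrays, per the file headers and the values themselves. The deposited detection p-value of each probe and array compares its signal with the negative control beads of the array, per the file headers. The deposited log2 values of the processed table were made by the authors by a method that is not stated, and the base follows from their slope against the intensities. There, 7 columns rank the probes exactly as the intensity column of the same sample, the column labelled ES replicate 3 ranks them as the intensity column of ES replicate 2, and the column labelled ES replicate 2 ranks them as no intensity column. The comparisons therefore use the intensities, and the processed values serve as an alternative.

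Intensities were read with R 4.3.3 and limma 3.58.1; figures were drawn with matplotlib 3.10.9. The function neqc fitted the background through the detection p-values, added an offset of 16, normalized by quantiles and took log2. Of 25697 probes, 23978 have 1 gene symbol, 0 several and 1719 none, and 23962 matched by Entrez ID in the gene table. Kept were 15090 probes with a detection p under 0.05 on at least 3 arrays, 14206 of them with a symbol. For a gene with several probes the brightest over all arrays was used, giving 10251 genes, 2772 of which have more than 1 detected probe. Among 454 named results, 87 concern genes with another detected probe, and in 23 a probe was not called the same way: Ifitm1, Slc16a3, Ung in DE against ES, Acta2, Actc1, Col18a1, Ddx4, Gadd45a, Gtse1, Ifitm1, Itgb4, Nusap1, Phc1, Pou5f1, Prrx1, Smarcc1, Tdgf1 in AFE against DE, Cdh2, Sesn2, Slc16a3, Sox7, Tapbp, Ung in AFE against ES. Detected probes numbered 12628 to 14352 per array and median intensities ran from 93.9 to 151.

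A linear model of limma with the 3 groups was fitted to all 9 arrays, with moderated statistics of eBayes, and p-values were adjusted by Benjamini and Hochberg over all genes tested; every adjusted p of a gene is of limma, and each adjusted p of a list is of fry or camera, both of limma. A gene is called at an adjusted p under 0.05, and calls of at least 2-fold are counted separately. The moderated F-test of limma compares the 3 groups. Lists were tested with fry, adjusted over 117 pairs of 39 lists and 3 comparisons. In a self-test on simulated arrays, 36%, 28% and 32% of genes set to 2-fold and 79%, 87% and 87% of those set to 4-fold were recovered in DE against ES, AFE against DE and AFE against ES, with 10, 8 and 7 false calls.

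Comparisons, lists, thresholds and alternatives were fixed before the data were examined. The 39 lists, named for what their members do, cover pluripotency, primed pluripotency, germ cell, mesendoderm, definitive endoderm, anterior foregut, posterior gut, extraembryonic endoderm, trophoblast, epithelial, basement membrane, EMT, fibroblast, neural, surface ectoderm, cardiac and lateral mesoderm, paraxial and axial mesoderm, blood and endothelium, 6 signalling pathways (Nodal and activin, BMP, Wnt, FGF and ERK, hedgehog and Notch) with retinoic acid, anterior and posterior Hox, S phase, mitosis, cell cycle inhibitors and p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, immediate early, unfolded protein and heat shock, interferon and antigen presentation, imprinted, DNA methylation and chromatin, and sex chromosome genes. Named genes are, per comparison, the 8 largest rises and 8 largest falls among calls of at least 2-fold without overlap between arrays, up to 4 members of each list with the largest change, and fixed landmark genes. Genes named by their level on single arrays outside this rule were chosen after their values were seen.

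The alternatives were no background correction or a background fitted without detection p-values and with an offset of 50, median scaling or cyclic loess, the authors' processed values, no filter or a stricter filter, the mean of a gene's probes or each probe by itself, only the 6 arrays compared, an intensity trend with robust moderation, the replicate block, a test against a fold of 1.5, camera, and leaving out each array. Leaving out ES 3, the only array on the second slide, is the comparison within slide 1. Added after the data were seen were the authors' values without the unmatched column, replicates 1 and 2 averaged, and both DE 3 and ES 3 left out. Probes without a gene symbol were not used here, except in the tests of each probe by itself.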

Results

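Mouse ES cells, in vitro derived definitive endoderm (DE) and in vitro derived anterior foregut cells (AFE) were compared on bead arrays, 3 arrays a group. Pluripotency genes such as Pou5f1 and Esrrb were highest in ES cells, endoderm genes such as Sox17, Hhex and Cer1 in DE, and Pax1 and Isl1, genes of the pharyngeal foregut, in AFE. Per the labels, endoderm was induced from day 2 with 5 nM GSKiXV and 5 µM IDE-1. After replating on day 6, cells received 500 nM A83-01, an inhibitor of TGF-beta family receptors, and 100 nM LDN193189, an inhibitor of BMP receptors. Of 10251 genes tested, 5713 (55.7%) differed among the 3 groups (moderated F-test of limma, adjusted p under 0.05). The first principal component (53.6% of the variance) separated ES cells from the rest, the second (25.4%) separated DE from AFE, and the third (10.1%) set DE 3 at -63.1 apart from DE 1 at 24.1 and DE 2 at 25.2.

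Changes are log2 differences of group means ± SE from limma, n = 3 arrays a group, and "rose" or "fell" is used only at an adjusted p under 0.05. A range marked "alternatives" gives the lowest and highest adjusted p over the other processing choices and the arrays left out. For a gene above background on 0 of the 3 arrays of its lower group, "at least" gives the fold against the lowest level detected on an array. Each SE pools the spread of all 3 groups, so an array apart in 1 group also widens the comparison of the other groups. Levels are log2 values on an array. For gene lists, the PValue of fry tests whether members moved, on balance, in 1 direction, and its PValue.Mixed tests for changes in either direction; neither compares a list with other genes. By the first, 71 of 117 list and comparison pairs passed, and by the second 106. With the correlation between genes estimated by camera, 0 of 117 passed, and with its preset correlation 41 passed. A direction given for a list is that of the fit to all arrays. A p without an array may belong to the other direction. Each group came from its own strain background and the ES cells carried no reporter, so strain, line and sort cannot be told apart from group. Nothing says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Across genes, replicates 1 and 2 correlated at 0.995 in DE, 0.994 in ES and 0.987 in AFE. With replicate 3 of their group they correlated at 0.931 to 0.979. If replicates 1 and 2 came from 1 culture, n is below 3 a group.

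**Figure D1:**
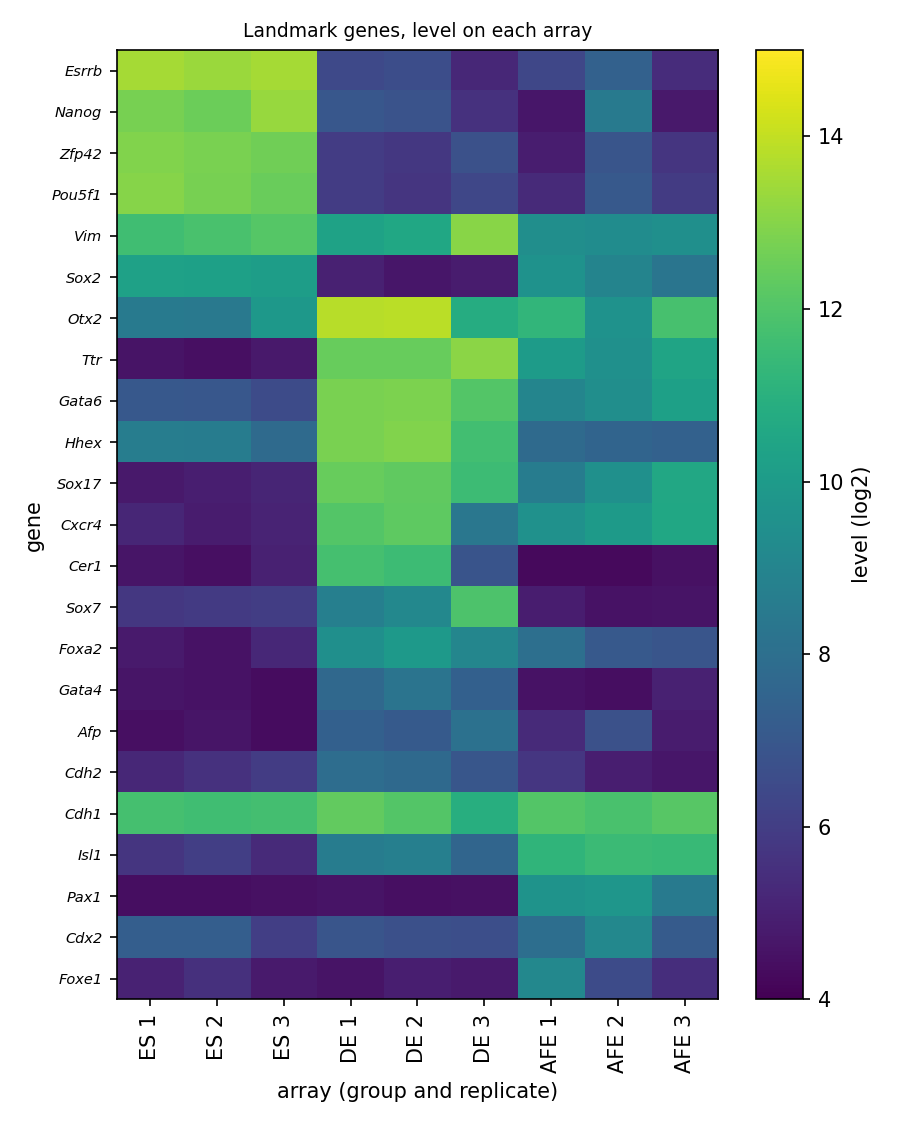
Levels (log2, colour scale) of the tested landmark genes (vertical axis) on each of the 9 arrays (horizontal axis), ordered by the group of highest mean. Pou5f1 lay above 12 on the 3 ES arrays, and Cer1 at 6.86 on DE 3 lay below DE 1 and DE 2.

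In DE against ES, many transcription factors of the endoderm rose and most tested pluripotency genes fell. Sox17, needed to form definitive endoderm, rose by 7.16 ± 0.45 (adjusted p = 3.93e-06), and with it rose the pioneer factors Foxa1 by 5.91 ± 0.33 and Foxa2 by 4.63 ± 0.34 and the zinc finger factors Gata6 by 5.70 ± 0.34 and Gata4 at least 6.44-fold. Esrrb, a nuclear receptor of naive ES cells, fell by 7.38 ± 0.49 (adjusted p = 5.98e-06), together with Pou5f1 by 6.74 ± 0.40, Utf1 by 6.66 ± 0.28, Zfp42 by 6.60 ± 0.45 and Nanog by 6.41 ± 0.89. Secreted carriers on the extraembryonic endoderm list were among the largest rises: Ttr at least 189.6-fold and Apoa1 at least 188-fold. Beside them rose the stomach protease precursor Pga5 by 7.98 ± 0.53, the chloride channel protein Clic6 by 7.26 ± 0.22, the forkhead factor Foxq1 by 6.95 ± 0.54 and the hexokinase relative Hkdc1 at least 82.2-fold. Among the largest falls were the oocyte gene Ooep at least 279.9-fold, the RNA-binding gene Rbmxl2 at least 98.1-fold and Inhba, which encodes an activin subunit, at least 63.2-fold.

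Of the 18 tested definitive endoderm genes, 17 rose, 0 fell and 1 did not pass, 17 and 0 adjusted over the list alone. Definitive endoderm genes had a median of 3.99, with fry adjusted p = 2.41e-04 and adjusted p = 0.327 with an estimated correlation. Among them Cxcr4, a chemokine receptor of migrating endoderm, rose by 5.86 ± 0.86 and Hhex, a factor of the anterior endoderm, by 4.09 ± 0.35. A Sox17 reporter line is among the lines named in the labels and the gate of the sort is not stated, so the Sox17 level describes sorted cells. The extraembryonic endoderm list had 24 tested genes, of which 19 rose, 0 fell and 5 did not pass, 19 and 1 adjusted over the list alone. Extraembryonic endoderm genes had a median of 2.84 (2.60 with bounded genes at their bound), with fry adjusted p = 1.64e-05 and adjusted p = 0.167 with an estimated correlation. Risen genes of the yolk sac layers were Rbp4 by 6.24 ± 0.46, Pth1r by 4.92 ± 0.59, Sox7 by 4.06 ± 0.67 and Afp at least 5.46-fold. Among 7 tested posterior gut genes, of 19 on the list, 4 rose, 1 fell and 2 did not pass, 4 and 1 adjusted over the list alone. Posterior gut genes had a median of 1.94 (1.67 with bounded genes at their bound), with fry adjusted p = 3.09e-04 and adjusted p = 0.434 with an estimated correlation. The liver and gut factor Hnf4a rose by 3.95 ± 0.24 and the brush border gene Vil1 at least 7.07-fold, while the hindgut factor Cdx1 fell by 2.51 ± 0.26. Of 17 anterior foregut genes, 6 rose and 3 fell, 6 and 3 adjusted over the list alone, and the list did not pass at a median of 0.11 and fry adjusted p = 0.186, the fry adjusted p being 0.00664 without DE 3 (alternatives 0.00664 to 0.771). Of these, Sox2, shared with pluripotent cells, fell at least 34.3-fold, Irx3 rose by 3.23 ± 0.60 and Isl1 by 2.64 ± 0.31, and the pharyngeal Pax1 did not pass (0.07 ± 0.30, adjusted p = 0.868).

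Of the 25 tested pluripotency genes, 0 rose, 23 fell and 2 did not pass, 0 and 23 adjusted over the list alone. Pluripotency genes had a median of -5.38 (-5.10 with bounded genes at their bound), with fry adjusted p = 1.64e-05 and adjusted p = 0.197 with an estimated correlation. The germ cell list had 7 tested genes, of which 0 rose, 6 fell and 1 did not pass, 0 and 6 adjusted over the list alone. Germ cell genes had a median of -2.11 (-1.81 with bounded genes at their bound), with fry adjusted p = 4.43e-06 and adjusted p = 0.167 with an estimated correlation. Dppa3 and Tex19.1, genes shared by germ cells and naive ES cells, fell: Dppa3 at least 15.8-fold and Tex19.1 by 5.09 ± 0.20. Among 15 tested DNA methylation and chromatin genes 1 rose, 7 fell and 7 did not pass, 1 and 8 adjusted over the list alone. DNA methylation and chromatin genes had a median of -0.75, with fry adjusted p = 0.00278 and adjusted p = 0.499 with an estimated correlation. The methyltransferase cofactor Dnmt3l fell by 6.02 ± 1.05 and the Polycomb gene Eed by 1.85 ± 0.20. Of 7 primed pluripotency genes, 4 rose and 1 fell, 4 and 1 adjusted over the list alone, and the list did not pass at a median of 0.99 and fry adjusted p = 0.573, the fry adjusted p being 8.5e-04 without DE 3 (alternatives 8.5e-04 to 0.948). Fgf5, a marker of the primed epiblast, rose by 3.91 ± 0.54. Of the 21 tested fibroblast genes, 1 rose, 12 fell and 8 did not pass, 2 and 12 adjusted over the list alone. Fibroblast genes had a median of -1.98, with fry adjusted p = 0.00325 and adjusted p = 0.498 with an estimated correlation. Per the labels ES cells were kept on fibroblast feeders. The collagen gene Col1a1 stood at 9.27, 9.04 and 10.58 on ES 1, 2 and 3 and the surface gene Thy1 at 11.34, 11.20 and 11.95, against means of 4.74 and 5.02 in DE. The list median lay 1.30 higher on ES 3 than on ES 1 and 2.

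Signalling targets moved both ways. The Notch list had 11 tested genes, of which 5 rose, 0 fell and 6 did not pass, 6 and 1 adjusted over the list alone. Notch genes had a median of 1.25, with fry adjusted p = 3.04e-04 and adjusted p = 0.323 with an estimated correlation. Among 12 tested BMP target genes 7 rose, 1 fell and 4 did not pass, 9 and 1 adjusted over the list alone. BMP target genes had a median of 1.17, with fry adjusted p = 3.32e-04 and adjusted p = 0.323 with an estimated correlation. Nrarp and Hey1, which respond to Notch, rose by 2.94 ± 0.30 and 2.45 ± 0.20. Of the 8 tested retinoic acid genes, 3 rose, 2 fell and 3 did not pass, 3 and 2 adjusted over the list alone. Retinoic acid genes had a median of -0.18 (-0.04 with bounded genes at their bound), the mean 0.77, the direction of the test up, with fry adjusted p = 1.85e-04 and adjusted p = 0.626 with an estimated correlation. Retinoic acid genes had a median of the other sign in alternatives: 0.37 under the authors' processed table (but -0.23 without its unmatched ES column), 1.29 under the stricter filter. Rarb, a receptor induced by retinoic acid, rose by 2.93 ± 0.21 and the degrading enzyme Cyp26a1 by 2.94 ± 0.47. The FGF and ERK target list had 13 tested genes, of which 1 rose, 5 fell and 7 did not pass, 1 and 5 adjusted over the list alone. FGF and ERK target genes had a median of -0.67, with fry adjusted p = 0.0128 and adjusted p = 0.505 with an estimated correlation. Among 13 tested Wnt target genes 2 rose, 5 fell and 6 did not pass, 2 and 5 adjusted over the list alone. Wnt target genes had a median of -0.20, with fry adjusted p = 0.0286 and adjusted p = 0.61 with an estimated correlation, the fry adjusted p being 0.0817 without DE 1, 0.11 without DE 3, 0.0911 without ES 1, 0.0917 without ES 2, 0.0823 without ES 3 (alternatives 5.05e-04 to 0.61). The Wnt inhibitor Dkk1 rose at least 24.9-fold and Notum, another, fell by 3.37 ± 0.63.

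DE 3 stood apart from DE 1 and 2 in several gene groups. Of 16 Nodal and activin target genes, 5 rose and 4 fell, 5 and 4 adjusted over the list alone. The list did not pass at a median of 0.60, the direction of the test down with all arrays and fry adjusted p = 0.72. Without DE 3, on which the list lay lower, the fry adjusted p was 2.95e-04 (alternatives 1.22e-04 to 0.985). Of 13 mesendoderm genes, 5 rose and 2 fell, 5 and 2 adjusted over the list alone, and the list did not pass at a median of 0.90 and fry adjusted p = 0.791, the fry adjusted p being 1.96e-04 without DE 3 (alternatives 1.28e-06 to 0.987). On DE 3 the median of the Nodal list lay -2.58 from DE 1 and 2: the feedback inhibitor Lefty1 stood at 14.99, 14.96 and 9.33 on DE 1, 2 and 3, the secreted Cer1 at 11.75, 11.52 and 6.86 and Eomes, a factor of the primitive streak, at 11.85, 11.61 and 8.69. Of 14 blood and endothelium genes, 3 rose and 0 fell, 3 and 0 adjusted over the list alone, and the list did not pass at a median of 0.99 (0.75 with bounded genes at their bound) and fry adjusted p = 0.129 (medians from -0.11 to 1.81 over alternatives). On DE 3 alone its median lay 3.49 higher and 11 of 14 members were at least 2-fold higher: the endothelial genes Emcn at 4.99, 4.72 and 13.23 on DE 1, 2 and 3, Esam at 7.45, 7.29 and 12.90 and Pecam1 at 4.77, 4.60 and 9.88. Kdr, Gata1 and Runx1 were not among them. The definitive endoderm list, which shares Cer1, Gsc, Lhx1 and Eomes with the Nodal or mesendoderm list, lay -1.17 from DE 1 and 2 on DE 3, with 11 of 18 members at least 2-fold lower, Cxcr4 at 12.05, 12.25 and 8.37 on DE 1, 2 and 3 among them. The epithelial list lay -1.03 from them, with 15 of 27 lower. The extraembryonic endoderm list lay 0.91 higher, with 11 of 24 members at least 2-fold higher, Sox7 and the laminin gene Lama1 among them. Some endoderm genes differed by less than 2-fold, with Ttr at 12.44, 12.44 and 13.10, Hnf4a at 9.97, 9.98 and 9.87 and Sox17 at 12.46, 12.30 and 11.55.

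**Figure D2:**
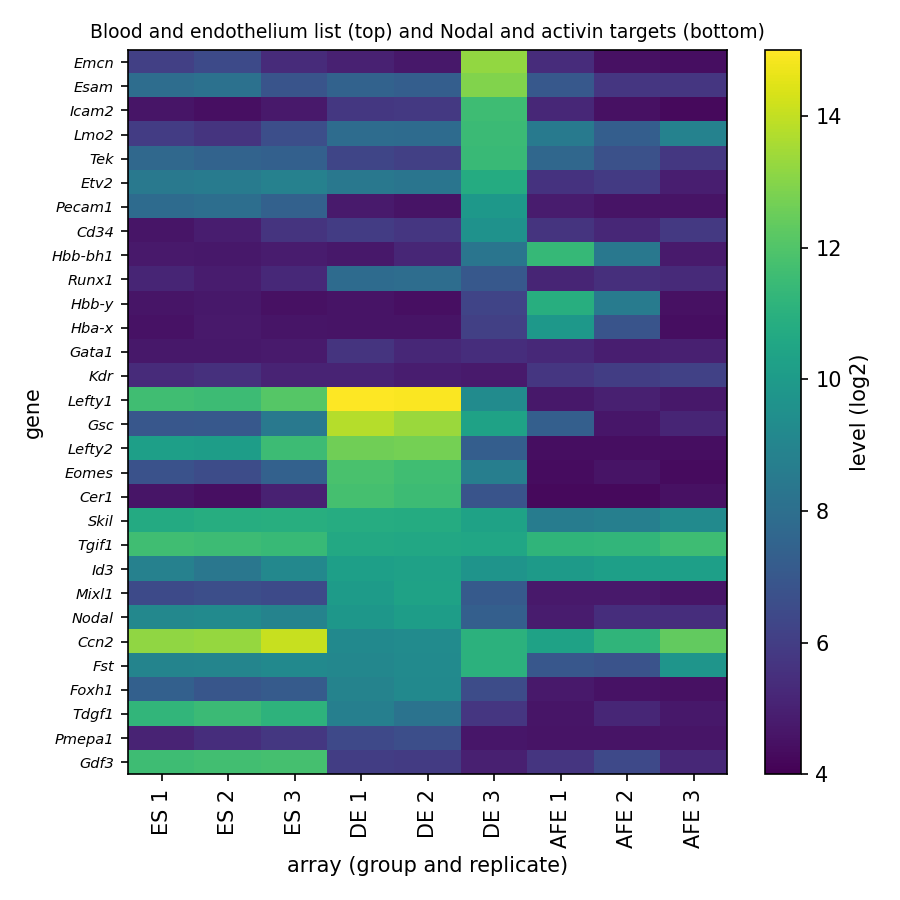
Levels (log2, colour scale) of the tested members of the blood and endothelium list and of the Nodal and activin targets (vertical axis) on each array (horizontal axis). Emcn stood at 13.23 on DE 3 and at most at 6.45 on the other arrays, and Lefty2 stood at 12.72 on DE 2 and 7.29 on DE 3.

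Of 27 epithelial genes, 8 rose and 4 fell, 9 and 6 adjusted over the list alone, and the list did not pass at a median of 0.51 and fry adjusted p = 0.225 (medians from -0.0662 to 0.71 over alternatives), the fry adjusted p being 4.5e-04 without DE 3 (alternatives 4.5e-04 to 0.802). Krt18 and Krt8, keratins of simple epithelia, rose by 2.93 ± 0.42 and 2.31 ± 0.39, as did the tight junction gene Cldn6 by 2.63 ± 0.28, while the adhesion gene Cdh1 did not pass (0.08 ± 0.33, adjusted p = 0.871, and 0.0384 without DE 3, alternatives 0.0384 to 0.945). Of the 14 tested basement membrane genes, 7 rose, 0 fell and 7 did not pass, 8 and 0 adjusted over the list alone. Basement membrane genes had a median of 1.22, with fry adjusted p = 0.00901 and adjusted p = 0.532 with an estimated correlation. Laminin and collagen IV chains rose: Lama1 by 3.96 ± 0.51, Col4a1 by 3.42 ± 0.35 and Col4a2 by 3.34 ± 0.51. On DE 3 the basement membrane list lay 0.88 higher than on DE 1 and 2, with 7 of 14 members at least 2-fold higher. Of 10 EMT genes, 2 rose and 1 fell, 2 and 0 adjusted over the list alone. The list did not pass at a median of -0.38 and a mean of 0.15 (medians from -0.66 to 0.33 over alternatives). With all arrays the direction of the test was up and fry adjusted p = 0.633. Without DE 3, on which the EMT list lay 1.46 higher than on DE 1 and 2, the fry adjusted p was 0.0287 (alternatives 0.00645 to 0.933). Its member Vim did not pass (-0.54 ± 0.59, adjusted p = 0.485, and 3.15e-04 without DE 3, alternatives 3.15e-04 to 0.951). The surface ectoderm list had 8 tested genes, of which 1 rose, 4 fell and 3 did not pass, 1 and 4 adjusted over the list alone. Surface ectoderm genes had a median of -0.83 (-0.67 with bounded genes at their bound), with fry adjusted p = 3.32e-04 and adjusted p = 0.434 with an estimated correlation. Among 11 tested neural genes 2 rose, 4 fell and 5 did not pass, 2 and 4 adjusted over the list alone. Neural genes had a median of -0.24, with fry adjusted p = 3.93e-04 and adjusted p = 0.505 with an estimated correlation. The neuronal gene Stmn2 fell by 4.70 ± 0.20. Of the 7 tested trophoblast genes, 3 rose, 1 fell and 3 did not pass, 5 and 1 adjusted over the list alone. Trophoblast genes had a median of 0.73 (0.70 with bounded genes at their bound), with fry adjusted p = 0.03 and adjusted p = 0.585 with an estimated correlation, the fry adjusted p being 0.0958 without DE 1, 0.0865 without DE 2, 0.0546 without AFE 1, 0.0689 without AFE 2, 0.052 without AFE 3, 0.0596 without ES 2 (alternatives 0.0014 to 0.599). The paraxial and axial mesoderm list had 7 tested genes, of which 3 rose, 1 fell and 3 did not pass, 3 and 1 adjusted over the list alone. Paraxial and axial mesoderm genes had a median of 0.56, with fry adjusted p = 0.011 and adjusted p = 0.505 with an estimated correlation, the fry adjusted p being 0.661 without DE 3 (alternatives 0.00347 to 0.661). Of 10 cardiac and lateral mesoderm genes, 2 rose and 1 fell, 2 and 1 adjusted over the list alone, and the list did not pass at a median of 0.06, the direction of the test down and fry adjusted p = 0.683 (medians from -0.12 to 0.15 over alternatives).

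Among 14 tested mitosis genes 0 rose, 8 fell and 6 did not pass, 0 and 8 adjusted over the list alone. Mitosis genes had a median of -0.65, with fry adjusted p = 0.00353 and adjusted p = 0.492 with an estimated correlation. Of 21 S phase genes, 0 rose and 8 fell, 0 and 8 adjusted over the list alone, and the list did not pass at a median of -0.50 and fry adjusted p = 0.0569, the fry adjusted p being 0.0467 without AFE 2, 2.5e-04 without AFE 3 (alternatives 2.5e-04 to 0.626). Bub1b and Cdc20, which act at the spindle checkpoint, fell: Bub1b by 1.43 ± 0.22 and Cdc20 by 1.15 ± 0.24. Of the 18 tested cell cycle inhibitor and p53 target genes, 1 rose, 6 fell and 11 did not pass, 1 and 6 adjusted over the list alone. Cell cycle inhibitor and p53 target genes had a median of -0.64, with fry adjusted p = 2.43e-04 and adjusted p = 0.284 with an estimated correlation. The cholesterol synthesis list had 15 tested genes, of which 11 rose, 0 fell and 4 did not pass, 12 and 0 adjusted over the list alone. Cholesterol synthesis genes had a median of 1.01, with fry adjusted p = 0.0108 and adjusted p = 0.499 with an estimated correlation. Among 23 tested oxidative phosphorylation genes 0 rose, 2 fell and 21 did not pass, 0 and 1 adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.17, with fry adjusted p = 2.71e-04 and adjusted p = 0.498 with an estimated correlation. Of 17 glycolysis genes, 6 rose and 1 fell, 6 and 2 adjusted over the list alone, and the list did not pass at a median of 0.21 and fry adjusted p = 0.0982, the fry adjusted p being 0.00532 without DE 3 (alternatives 0.00532 to 0.957). Of the 17 tested imprinted genes, 9 rose, 3 fell and 5 did not pass, 10 and 3 adjusted over the list alone. Imprinted genes had a median of 1.38, with fry adjusted p = 1.64e-05 and adjusted p = 0.323 with an estimated correlation. Nnat and Mest, expressed from the paternal copy, rose by 4.56 ± 0.52 and 3.31 ± 0.28, while Phlda2, a brake on placental growth, fell by 4.68 ± 0.36.

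The interferon and antigen presentation list had 13 tested genes, of which 0 rose, 8 fell and 5 did not pass, 1 and 11 adjusted over the list alone. Interferon and antigen presentation genes had a median of -0.98, with fry adjusted p = 1.21e-04 and adjusted p = 0.167 with an estimated correlation. Among 14 tested immediate early genes 2 rose, 8 fell and 4 did not pass, 2 and 8 adjusted over the list alone. Immediate early genes had a median of -1.41, with fry adjusted p = 0.0109 and adjusted p = 0.613 with an estimated correlation. Fos, which also responds to dissociation, fell by 4.48 ± 0.53. Of the 15 tested unfolded protein and heat shock genes, 3 rose, 7 fell and 5 did not pass, 3 and 7 adjusted over the list alone. Unfolded protein and heat shock genes had a median of -0.84, with fry adjusted p = 0.0284 and adjusted p = 0.61 with an estimated correlation, the fry adjusted p being 0.0678 without DE 1, 0.0645 without DE 2, 0.116 without ES 1, 0.0803 without ES 2 (alternatives 0.00702 to 0.61). Of 5 anterior Hox genes, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, and the list did not pass at a median of 0.34 (0.30 with bounded genes at their bound) and fry adjusted p = 0.546 (medians from -0.34 to 0.83 over alternatives). Of 15 posterior Hox genes, 0 rose and 1 fell, 0 and 0 adjusted over the list alone, and the list did not pass at a median of -0.27 and fry adjusted p = 0.573 (medians from -0.65 to 0.0862 over alternatives), the fry adjusted p being 0.00278 without DE 3 (alternatives 0.00278 to 0.975). The medians of these Hox lists lay 2.47 and 1.90 higher on DE 3 than on DE 1 and 2. Of 2 sex chromosome genes, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, and the list did not pass at a median of 1.01 and fry adjusted p = 0.262, the fry adjusted p being 0.00493 without ES 3 (alternatives 0.00188 to 0.745). Its Y-linked member Eif2s3y stood at 7.68, 7.88 and 11.18 on ES 1, 2 and 3 and between 9.81 and 11.2 on the DE and AFE arrays, so that it did not pass in DE against ES (1.38 ± 0.78, adjusted p = 0.178, and 4.97e-04 without ES 3, alternatives 8.91e-05 to 0.66).

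In all, 2276 genes rose and 2227 fell, 43.9% of those tested, and 1458 and 1403 of them by at least 2-fold, of which 424 folds are bounds. Before adjustment 5342 genes had p under 0.05, and in 56.7% of genes the arrays of both groups did not overlap, where chance gives 10%. ES 3 lay alone on the second slide: without it, which is the comparison within slide 1, 1943 genes rose and 2018 fell, and the medians were 4.20 for definitive endoderm, -5.44 for pluripotency, 2.92 for extraembryonic endoderm and -1.57 for fibroblast genes. Under median scaling 2481 genes rose and 1763 fell (58.5% higher, against 50.5%). Without DE 3 and ES 3 together, 2545 genes rose and 2394 fell. With replicates 1 and 2 of each group averaged to 1 sample, 946 genes rose and 1053 fell, and by the authors' values with columns as labelled 361 and 306, or 1916 and 1873 without the unmatched ES column. Genes detected on only 1 or 2 arrays of their lower group, so that the log2 change given rests partly on background, were Cdx1, Cxcr4, Cyp26a1, Foxa1, Foxa2, Nnat, Notum, Pth1r, Rarb, Rbp4, Sox17 and Utf1.

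In AFE against DE, many genes of the pharynx and foregut rose while many Nodal-responsive and extraembryonic endoderm genes fell. Pax1, a factor of the pharyngeal pouches, rose at least 18.5-fold (adjusted p = 1.66e-05), with the foregut factor Sox2 at least 14.4-fold, the signal Shh by 3.54 ± 0.25, made by foregut epithelium, and the homeodomain factors Isl1 by 3.05 ± 0.31 and Nkx2-3 by 4.54 ± 0.83. Nkx2-3 stood at 12.08, 10.69 and 7.96 on AFE 1, 2 and 3. Lefty1, which restrains Nodal, fell at least 218-fold (adjusted p = 0.00186), beside the organizer genes Gsc by 6.78 ± 0.94 and Lhx1 at least 76.4-fold and the streak factor Eomes at least 42-fold. Large rises were also seen for the secreted signals Gdnf by 5.37 ± 0.65, Cxcl12 by 5.24 ± 0.58 and Wnt6 at least 23.4-fold, the carboxylesterase Ces1d at least 39.5-fold and the growth brake Phlda2 by 4.87 ± 0.36, and large falls for Pga5 by 8.71 ± 0.53, Foxq1 by 8.09 ± 0.54, Apoa1 by 6.65 ± 0.39 and Srgn at least 67-fold.

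The anterior foregut list had 17 tested genes, of which 11 rose, 0 fell and 6 did not pass, 12 and 0 adjusted over the list alone. Anterior foregut genes had a median of 2.44 (2.00 with bounded genes at their bound), with fry adjusted p = 5.6e-05 and adjusted p = 0.167 with an estimated correlation. The thyroid factor Foxe1 did not pass (2.25 ± 0.75, adjusted p = 0.0571, without AFE 1 0.0483 and without AFE 3 0.0135, alternatives 0.0135 to 0.201) and stood at 9.14, 6.50 and 5.42 on AFE 1, 2 and 3. Pax9, the gene of another reporter line named in the labels, was detected on 2 arrays, Nkx2-1 on 1 and Pax6 on 0, and Tbx1, Epcam and T had no named probe, so none of these were tested. Among 18 tested definitive endoderm genes 1 rose, 11 fell and 6 did not pass, 1 and 12 adjusted over the list alone. Definitive endoderm genes had a median of -2.35 (-2.31 with bounded genes at their bound), with fry adjusted p = 0.00417 and adjusted p = 0.383 with an estimated correlation. Of the 24 tested extraembryonic endoderm genes, 1 rose, 18 fell and 5 did not pass, 2 and 20 adjusted over the list alone. Extraembryonic endoderm genes had a median of -1.89, with fry adjusted p = 6.33e-05 and adjusted p = 0.167 with an estimated correlation. Hhex fell by 4.87 ± 0.35, with Sox17 by 2.53 ± 0.45, Foxa2 by 2.16 ± 0.34, Gata6 by 2.99 ± 0.34 and Gata4 at least 5.49-fold, and in the yolk sac list Sox7 at least 24.5-fold, Ttr by 2.67 ± 0.27 and Afp by 1.91 ± 0.44. The chemokine receptor Cxcr4 and the head factor Otx2 did not pass (Cxcr4 -0.85 ± 0.86, adjusted p = 0.511, Otx2 -1.96 ± 0.85, adjusted p = 0.126), and without DE 3 the adjusted p of limma was 5.5e-04 and 0.00572 (alternatives 5.5e-04 to 0.974 and 0.00562 to 0.542). The posterior gut list had 7 tested genes, of which 1 rose, 2 fell and 4 did not pass, 2 and 3 adjusted over the list alone. Posterior gut genes had a median of 0.02, the mean -0.73, the direction of the test down, with fry adjusted p = 0.00413 and adjusted p = 0.505 with an estimated correlation. Posterior gut genes had a median of the other sign in alternatives: -0.28 without DE 1, -0.50 without DE 2, -0.17 without DE 3, -0.09 without AFE 1, -0.18 without AFE 2, -0.08 under a background fitted without detection p-values and with an offset of 50, -0.10 under no background correction, -0.20 under median scaling, -0.03 under cyclic loess, -0.10 under the authors' processed table, -0.02 under the mean of a gene's probes, -0.10 under the authors' table without its unmatched ES column, -0.42 under replicates 1 and 2 averaged, -0.17 under leaving out DE 3 and ES 3. Hnf4a fell by 3.42 ± 0.24 and Vil1 by 2.75 ± 0.30, and Cdx2 did not pass (1.36 ± 0.48, adjusted p = 0.0711, and 0.0241 without AFE 3, alternatives 0.0241 to 0.301).

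Among 16 tested Nodal and activin target genes 1 rose, 10 fell and 5 did not pass, 2 and 12 adjusted over the list alone. Nodal and activin target genes had a median of -3.17 (-2.56 with bounded genes at their bound), with fry adjusted p = 0.00785 and adjusted p = 0.434 with an estimated correlation. Of the 13 tested mesendoderm genes, 1 rose, 8 fell and 4 did not pass, 2 and 8 adjusted over the list alone. Mesendoderm genes had a median of -2.62, with fry adjusted p = 0.0229 and adjusted p = 0.505 with an estimated correlation, the fry adjusted p being 0.0621 without DE 1, 0.0579 without DE 2, 0.0624 without AFE 1, 0.0689 without AFE 2, 0.0626 without AFE 3 (alternatives 2.86e-07 to 0.505). The primed pluripotency list had 7 tested genes, of which 1 rose, 3 fell and 3 did not pass, 1 and 3 adjusted over the list alone. Primed pluripotency genes had a median of -1.73 (-0.86 with bounded genes at their bound), with fry adjusted p = 0.03 and adjusted p = 0.541 with an estimated correlation, the fry adjusted p being 0.0872 without DE 1, 0.0958 without DE 2, 0.0593 without AFE 1, 0.107 without AFE 2, 0.0658 without AFE 3, 0.0581 without ES 1, 0.0552 without ES 2 (alternatives 7.75e-05 to 0.541). Fgf5 fell by 6.54 ± 0.54. Lefty2, induced by Nodal, fell at least 46.9-fold and Cer1 at least 26.4-fold. Among 12 tested BMP target genes 3 rose, 2 fell and 7 did not pass, 3 and 2 adjusted over the list alone. BMP target genes had a median of 0.06, with fry adjusted p = 0.0284 and adjusted p = 0.93 with an estimated correlation, the fry adjusted p being 0.0508 without DE 1, 0.0595 without DE 2, 0.0719 without DE 3, 0.0563 without AFE 2, 0.139 without AFE 3, 0.0642 without ES 2 (alternatives 0.0104 to 0.93). BMP target genes had a median of the other sign in alternatives: -0.05 without DE 3, -0.08 without AFE 3, -0.16 under median scaling, -0.05 under leaving out DE 3 and ES 3. Id4 and Id2, induced by BMP, rose: Id4 by 4.13 ± 0.29 and Id2 by 2.61 ± 0.27, while the BMP binding protein Bmper fell by 4.33 ± 0.56. Of the 13 tested Wnt target genes, 7 rose, 2 fell and 4 did not pass, 8 and 2 adjusted over the list alone. Wnt target genes had a median of 1.23, with fry adjusted p = 0.00131 and adjusted p = 0.327 with an estimated correlation. The receptor Tnfrsf19 rose by 4.12 ± 0.28 and the cyclin Ccnd1 by 1.78 ± 0.39, and Dkk1 fell by 3.75 ± 0.82. The hedgehog list had 5 tested genes, of which 3 rose, 2 fell and 0 did not pass, 3 and 2 adjusted over the list alone. Hedgehog genes had a median of 0.98 (0.59 with bounded genes at their bound), with fry adjusted p = 1.21e-04 and adjusted p = 0.541 with an estimated correlation. Hedgehog genes had a median of the other sign in alternatives: -0.14 under the stricter filter. Among 8 tested retinoic acid genes 4 rose, 2 fell and 2 did not pass, 5 and 2 adjusted over the list alone. Retinoic acid genes had a median of 0.93 (0.50 with bounded genes at their bound), with fry adjusted p = 1.83e-04 and adjusted p = 0.498 with an estimated correlation. The binding protein Crabp2 rose by 2.52 ± 0.45 and the receptor Rarb by 1.97 ± 0.21, and the degrading enzyme Cyp26a1 fell by 2.40 ± 0.47.

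**Figure D3:**
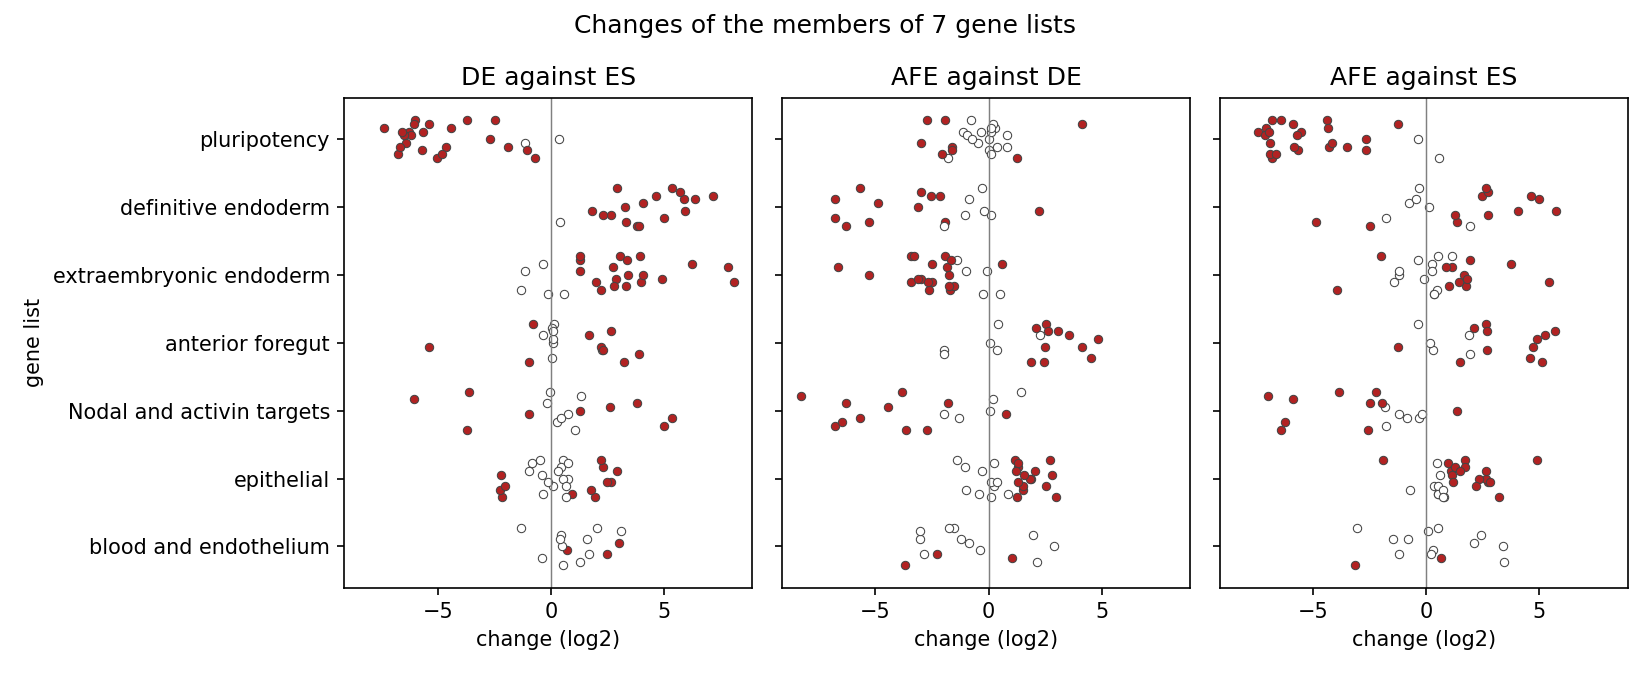
Change (log2, horizontal axis) of each tested member of 7 gene lists (vertical axis, offset within a row for display) in the 3 comparisons, filled where the adjusted p was under 0.05. The anterior foregut list had 11 risen members of 17 in AFE against DE, and the pluripotency list 23 fallen members of 25 in DE against ES.

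Of the 27 tested epithelial genes, 16 rose, 0 fell and 11 did not pass, 16 and 2 adjusted over the list alone. Epithelial genes had a median of 1.25 (1.22 with bounded genes at their bound), with fry adjusted p = 0.00976 and adjusted p = 0.499 with an estimated correlation. The tight junction gene Cldn4 rose by 2.96 ± 0.41 and the membrane protease Prss8 by 2.71 ± 0.26, and Cdh1 did not pass (0.25 ± 0.33, adjusted p = 0.621). Under median scaling the epithelial list had a median of 0.93 but did not pass (adjusted p = 0.0708, alternatives 3.23e-04 to 0.499). The EMT list had 10 tested genes, of which 0 rose, 4 fell and 6 did not pass, 0 and 5 adjusted over the list alone. EMT genes had a median of -0.71, with fry adjusted p = 0.0227 and adjusted p = 0.434 with an estimated correlation, the fry adjusted p being 0.0791 without DE 3, 0.0619 without AFE 2, 0.0607 without AFE 3 (alternatives 0.00751 to 0.434). Snai1 and Zeb1, repressors of epithelial genes, fell: Snai1 by 2.78 ± 0.51 and Zeb1 by 2.58 ± 0.62, with the cadherin Cdh2 by 2.43 ± 0.35. Among 8 tested surface ectoderm genes 3 rose, 0 fell and 5 did not pass, 4 and 0 adjusted over the list alone. Surface ectoderm genes had a median of 0.49, with fry adjusted p = 2.61e-04 and adjusted p = 0.323 with an estimated correlation. Trp63, a factor of stratified epithelia, rose at least 4-fold and the homeodomain gene Dlx3 by 3.02 ± 0.36. Of the 11 tested neural genes, 0 rose, 4 fell and 7 did not pass, 0 and 4 adjusted over the list alone. Neural genes had a median of -0.02, with fry adjusted p = 0.0121 and adjusted p = 0.498 with an estimated correlation, the fry adjusted p being 0.052 without AFE 3 (alternatives 0.00298 to 0.498). Neural genes had a median of the other sign in alternatives: 0.01 without DE 1, 0.00204 without DE 3, 0.08 under cyclic loess, 0.02 under replicates 1 and 2 averaged, 0.00204 under leaving out DE 3 and ES 3.

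Single AFE arrays differed in genes of other tissues. Of 14 blood and endothelium genes, 1 rose and 2 fell, 1 and 2 adjusted over the list alone, and the list did not pass at a median of -1.38 (-1.15 with bounded genes at their bound) and fry adjusted p = 0.265. On DE 3, 1 of the arrays compared, this list lay 3.49 higher than on DE 1 and 2. The embryonic globin Hbb-bh1 stood at 11.37, 8.39 and 4.81 on AFE 1, 2 and 3 and Hba-x at 9.85, 6.87 and 4.43. Of 21 fibroblast genes, 2 rose and 2 fell, 2 and 1 adjusted over the list alone, and the list did not pass at a median of 0.69 and fry adjusted p = 0.416. Col3a1, a collagen of connective tissue, stood at 9.49, 8.56 and 5.02. Of 10 cardiac and lateral mesoderm genes, 2 rose and 1 fell, 2 and 1 adjusted over the list alone, and the list did not pass at a median of 0.12 (0.02 with bounded genes at their bound) and fry adjusted p = 0.613 (medians from -0.0951 to 0.26 over alternatives). Nppb, a gene of heart muscle chosen after its values were seen, stood at 5.06, 5.17 and 9.01. Of 25 pluripotency genes, 2 rose and 6 fell, 3 and 6 adjusted over the list alone, and the list did not pass at a median of -0.33 and fry adjusted p = 0.72 (medians from -0.69 to 0.0407 over alternatives), the fry adjusted p being 0.00867 without AFE 2 (alternatives 0.00867 to 0.972). Its median was 0.0407 without AFE 1 and 0.00919 without AFE 3. On AFE 2 the median of the pluripotency list lay 0.98 higher than on AFE 1 and 3. Nanog stood at 4.68, 8.48 and 4.76 and did not pass (-0.48 ± 0.89, adjusted p = 0.74, and 0.03 without AFE 2, alternatives 0.03 to 0.958), and Dppa4 stood at 4.74, 7.88 and 4.70.

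The mitosis list had 14 tested genes, of which 9 rose, 0 fell and 5 did not pass, 9 and 0 adjusted over the list alone. Mitosis genes had a median of 0.87, with fry adjusted p = 0.00187 and adjusted p = 0.362 with an estimated correlation. Of 21 S phase genes, 1 rose and 0 fell, 0 and 0 adjusted over the list alone, and the list did not pass at a median of 0.18 and fry adjusted p = 0.58 (medians from -0.14 to 0.42 over alternatives), the fry adjusted p being 9.47e-04 without AFE 3 (alternatives 9.47e-04 to 0.947). The mitotic kinase Aurka rose by 1.31 ± 0.17. Among 18 tested cell cycle inhibitor and p53 target genes 5 rose, 1 fell and 12 did not pass, 8 and 1 adjusted over the list alone. Cell cycle inhibitor and p53 target genes had a median of 0.51, with fry adjusted p = 0.00469 and adjusted p = 0.435 with an estimated correlation. Of the 13 tested interferon and antigen presentation genes, 3 rose, 0 fell and 10 did not pass, 3 and 0 adjusted over the list alone. Interferon and antigen presentation genes had a median of 0.50, with fry adjusted p = 0.00443 and adjusted p = 0.327 with an estimated correlation. Tap1, which loads antigen peptides, rose at least 1.62-fold. Of 14 immediate early genes, 0 rose and 4 fell, 0 and 7 adjusted over the list alone, and the list did not pass at a median of -0.91 (-0.53 with bounded genes at their bound) and fry adjusted p = 0.079, the fry adjusted p being 0.00698 without AFE 3 (alternatives 0.00698 to 0.505). Of 17 imprinted genes, 2 rose and 2 fell, 2 and 2 adjusted over the list alone, and the list did not pass at a median of -0.03, the mean 0.32, the direction of the test up and fry adjusted p = 0.0989 (medians from -0.17 to 0.19 over alternatives), the fry adjusted p being 0.00184 without DE 3, 0.0237 without AFE 3 (alternatives 0.00184 to 0.947). Imprinted genes had a median of the other sign in alternatives: 0.19 without AFE 3, 0.13 under the stricter filter.

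In all, 1322 genes rose and 1036 fell, 23% of those tested, and 703 and 697 of them by at least 2-fold, of which 194 folds are bounds. Before adjustment 3756 genes had p under 0.05, and the arrays did not overlap in 38.6% of genes, where chance gives 10%. The share that rose among changed genes, 56.1%, depended on the scaling: under median scaling 652 genes rose and 1298 fell (33.4% higher), a scaling that moved the median of all genes by -0.19. By the values that the authors processed, 392 rose and 491 fell (44.4%), and without its unmatched ES column 933 and 1111 (45.6%). The counts also depended on single arrays: 812 rose and 694 fell without DE 1, 742 and 679 without DE 2, and 1866 and 1590 without DE 3 and ES 3. With replicates 1 and 2 averaged, 191 genes rose and 196 fell. Genes detected on only 1 or 2 arrays of their lower group, so that the log2 change given rests partly on background, were Afp, Bmper, Cdh2, Cyp26a1, Dkk1, Dlx3, Fgf5, Foxq1, Gdnf, Gsc and Vil1.

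In AFE against ES, many foregut and epithelial genes rose and most tested pluripotency genes fell. Isl1, a homeodomain factor of the pharyngeal endoderm, rose by 5.69 ± 0.31 (adjusted p = 2.29e-06), with the forkhead factor Foxa1 by 5.72 ± 0.33 and the signal Shh by 5.23 ± 0.25. Esrrb fell by 7.09 ± 0.49 (adjusted p = 7.84e-06), with Zfp42 by 6.93 ± 0.45, Pou5f1 by 6.65 ± 0.40 and Nanog by 6.89 ± 0.89. Sox2, shared by ES cells and foregut, fell by 1.26 ± 0.30 only, and its sign was the other way in the authors' processed table with columns as labelled (0.47) but not without its unmatched ES column (-1.40). Other large rises were Capn6 by 6.90 ± 0.42, Igfbp5 by 6.53 ± 0.57, Clic6 by 5.91 ± 0.22 and Car14 by 5.75 ± 0.30, and other large falls Ooep by 7.61 ± 0.71, Dppa4 by 7.41 ± 1.20, Klf2 by 7.14 ± 1.06, Tex19.1 at least 89.5-fold and Lefty1 at least 86.4-fold.

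The pluripotency list had 25 tested genes, of which 0 rose, 23 fell and 2 did not pass, 0 and 23 adjusted over the list alone. Pluripotency genes had a median of -5.70, with fry adjusted p = 1.64e-05 and adjusted p = 0.167 with an estimated correlation. Among 17 tested anterior foregut genes 11 rose, 1 fell and 5 did not pass, 12 and 1 adjusted over the list alone. Anterior foregut genes had a median of 2.65 (2.02 with bounded genes at their bound), with fry adjusted p = 2.2e-05 and adjusted p = 0.201 with an estimated correlation. Irx3 rose by 5.11 ± 0.60 and Pax1 at least 18.8-fold. Of the 18 tested definitive endoderm genes, 10 rose, 2 fell and 6 did not pass, 10 and 2 adjusted over the list alone. Definitive endoderm genes had a median of 1.64, with fry adjusted p = 0.0093 and adjusted p = 0.626 with an estimated correlation. Sox17 rose by 4.63 ± 0.45 and Cxcr4 by 5.00 ± 0.86. Gata4 and Cer1 did not pass (Gata4 0.14 ± 0.25, adjusted p = 0.677, and Cer1 -0.32 ± 1.05, adjusted p = 0.828). The SE of Cer1 and of Cxcr4 includes the spread of the DE arrays, where DE 3 stood apart for both genes. The extraembryonic endoderm list had 24 tested genes, of which 10 rose, 2 fell and 12 did not pass, 10 and 2 adjusted over the list alone. Extraembryonic endoderm genes had a median of 0.51, with fry adjusted p = 0.00521 and adjusted p = 0.541 with an estimated correlation. Ttr, which carries thyroid hormone and retinol, rose at least 29.8-fold, and Afp did not pass (1.14 ± 0.44, adjusted p = 0.0631, without DE 3 0.0401 and without AFE 3 0.0227, alternatives 0.0199 to 0.186). Among 7 tested posterior gut genes 2 rose, 2 fell and 3 did not pass, 3 and 2 adjusted over the list alone. Posterior gut genes had a median of 0.64 (0.53 with bounded genes at their bound), with fry adjusted p = 0.00521 and adjusted p = 0.626 with an estimated correlation. Posterior gut genes had a median of the other sign in alternatives: -0.13 under the authors' processed table (but 0.73 without its unmatched ES column). Of the 27 tested epithelial genes, 16 rose, 1 fell and 10 did not pass, 17 and 1 adjusted over the list alone. Epithelial genes had a median of 1.13, with fry adjusted p = 0.00239 and adjusted p = 0.498 with an estimated correlation. The protease Prss8 rose by 4.92 ± 0.26 and the keratin Krt19 by 3.20 ± 0.27.

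The fibroblast list had 21 tested genes, of which 0 rose, 10 fell and 11 did not pass, 0 and 10 adjusted over the list alone. Fibroblast genes had a median of -0.98 (-0.74 with bounded genes at their bound), with fry adjusted p = 0.0107 and adjusted p = 0.505 with an estimated correlation. The matrix crosslinking gene Lox fell at least 80.4-fold and stood at 11.15, 11.28 and 12.52 on ES 1, 2 and 3. Among 14 tested basement membrane genes 9 rose, 2 fell and 3 did not pass, 9 and 3 adjusted over the list alone. Basement membrane genes had a median of 1.57 (1.35 with bounded genes at their bound), with fry adjusted p = 0.0198 and adjusted p = 0.626 with an estimated correlation, the fry adjusted p being 0.0608 without ES 1, 0.0628 without ES 2 (alternatives 0.00287 to 0.626). Of the 8 tested retinoic acid genes, 5 rose, 0 fell and 3 did not pass, 5 and 0 adjusted over the list alone. Retinoic acid genes had a median of 1.18, with fry adjusted p = 9.61e-06 and adjusted p = 0.323 with an estimated correlation. Rarb rose by 4.90 ± 0.21. The Nodal and activin target list had 16 tested genes, of which 1 rose, 9 fell and 6 did not pass, 1 and 10 adjusted over the list alone. Nodal and activin target genes had a median of -2.08 (-1.80 with bounded genes at their bound), with fry adjusted p = 0.00475 and adjusted p = 0.498 with an estimated correlation. Among 13 tested mesendoderm genes 1 rose, 5 fell and 7 did not pass, 1 and 7 adjusted over the list alone. Mesendoderm genes had a median of -1.56 (-1.21 with bounded genes at their bound), with fry adjusted p = 0.0355 and adjusted p = 0.626 with an estimated correlation, the fry adjusted p being 0.0817 without AFE 1, 0.0886 without AFE 2, 0.0795 without AFE 3, 0.0737 without ES 1, 0.0857 without ES 2, 0.102 without ES 3 (alternatives 2.03e-06 to 0.626). Of the 12 tested BMP target genes, 7 rose, 1 fell and 4 did not pass, 8 and 1 adjusted over the list alone. BMP target genes had a median of 1.16, with fry adjusted p = 8.8e-05 and adjusted p = 0.323 with an estimated correlation. The FGF and ERK target list had 13 tested genes, of which 0 rose, 8 fell and 5 did not pass, 0 and 8 adjusted over the list alone. FGF and ERK target genes had a median of -1.12 (-0.81 with bounded genes at their bound), with fry adjusted p = 0.00278 and adjusted p = 0.434 with an estimated correlation. The ERK target Egr1 fell by 4.13 ± 0.57 and the feedback inhibitor Spry4 by 3.27 ± 0.63. Among 17 tested imprinted genes 10 rose, 3 fell and 4 did not pass, 11 and 3 adjusted over the list alone. Imprinted genes had a median of 1.59, with fry adjusted p = 1.15e-05 and adjusted p = 0.322 with an estimated correlation. The growth factor Igf2 rose by 3.00 ± 0.44 and the zinc finger gene Peg3 by 2.70 ± 0.18.

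Of the 14 tested immediate early genes, 0 rose, 9 fell and 5 did not pass, 0 and 9 adjusted over the list alone. Immediate early genes had a median of -1.89, with fry adjusted p = 0.00179 and adjusted p = 0.435 with an estimated correlation. The glycolysis list had 17 tested genes, of which 6 rose, 2 fell and 9 did not pass, 6 and 2 adjusted over the list alone. Glycolysis genes had a median of 0.33, with fry adjusted p = 0.00469 and adjusted p = 0.585 with an estimated correlation. Of 14 mitosis genes, 3 rose and 0 fell, 1 and 0 adjusted over the list alone, and the list did not pass at a median of 0.23 and fry adjusted p = 0.446 (medians from -0.14 to 0.31 over alternatives). Mitosis genes had a median of the other sign in alternatives: -0.14 under the authors' table without its unmatched ES column. Of 2 sex chromosome genes, 0 rose and 0 fell, 0 and 0 adjusted over the list alone, and the list did not pass at a median of 1.27 and fry adjusted p = 0.19, the fry adjusted p being 0.0032 without ES 3 (alternatives 0.0014 to 0.724). Fos, an early response gene, fell by 5.98 ± 0.53, and Eif2s3y did not pass (1.92 ± 0.78, adjusted p = 0.0726, and 2.01e-04 without ES 3, alternatives 3.44e-05 to 0.332).

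In all, 2342 genes rose and 1977 fell, 42.1% of those tested, and 1488 and 1270 of them by at least 2-fold, of which 493 folds are bounds. Before adjustment 5217 genes had p under 0.05, and the arrays did not overlap in 57.6% of genes, where chance gives 10%. Without ES 3, that is within slide 1, 2049 genes rose and 1833 fell, and the medians were 2.60 for anterior foregut, -5.83 for pluripotency, 1.09 for epithelial and -0.66 for fibroblast genes. Without DE 3 and ES 3, 2627 rose and 2353 fell, and with replicates 1 and 2 averaged 1094 rose and 950 fell. The balance turned with the scaling: under median scaling 1764 rose and 2004 fell, and by the authors' values without the unmatched ES column 1688 and 1926, against 699 and 636 with columns as labelled. With the latter the median of all genes moved by -0.11. Genes detected on only 1 or 2 arrays of their lower group, so that the log2 change given rests partly on background, were Car14, Cxcr4, Dppa4, Esrrb, Foxa1, Klf2, Nanog, Ooep, Rarb, Shh, Sox17, Spry4 and Zfp42.

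Against ES cells, DE and AFE shared many changes: 1361 genes rose in both, such as Foxa1 and Clic6, 1443 fell in both, such as Esrrb and Zfp42, and 81 moved in opposite directions. With replicates 1 and 2 averaged, 507 rose and 663 fell in both, and by the authors' values with columns as labelled 148 and 139, or 1027 and 1269 without the unmatched ES column. Independent lists of these sizes would share 520.0, 429 and 948 genes, and 100 simulations of unchanged groups sharing the ES arrays gave 0 of each. The simulation leaves out the effects and the independent lists leave out the shared arrays, whether of ES, DE or AFE, so neither measures what sharing adds to these counts, and the same holds for the counts below. Of genes higher in DE, 59.8% were also higher in AFE, and of genes lower in DE 64.8% were also lower in AFE. Across genes, which are not independent replicates, the changes correlated at r = 0.727 against a simulated 0.502, with a covariance of 1.13 against a simulated 0.0609. The ES arrays are shared and too few to be divided, so part of the excess may come from them. Other genes had their highest or lowest mean in DE: 626 genes, among them Cer1 and Gsc, were higher in DE than in both ES and AFE (independent lists 230.0, highest of 100 simulations 1), and 508, among them Sox2 and Phlda2, were lower in DE than in both (287, highest simulated 1). Genes higher in AFE than in both other groups numbered 709, such as Pax1 and Isl1 (302 from independent lists, 0 simulated), and genes lower in AFE than in both 324, such as Lefty1 (199.8 and 0).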

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

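All tests in this part were chosen, or their criteria written, after the results were seen.

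In the authors' processed values, the column labelled ES replicate 2 stood out because it carries an endoderm signal that the other ES columns lack. The median of the definitive endoderm list lies 5.15 above them, and 18 of 18 members are at least 2-fold higher. Cer1 is at 11.6 against 3.84 and 2.95, and Pou5f1 at 6.32 against 12.9 and 12.7. The authors' normalization is argued against, since the column correlates with the intensities of ES 2 at 0.88 (Spearman). Values of another array under this label remain a possible explanation: no intensity column exceeds 0.926, while each other processed column has a match. The intensities used here do not come from that column, and no biological explanation was tested.

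DE 3 stands apart from DE 1 and 2, and a shift shared by genes of the same level is argued against. For it, 10000 random lists of matched level gave a highest median of 1.07, against 3.49 for the blood and endothelium list. That list was chosen after its values were seen and normalization aligns arrays, so array quality is not excluded. Raw upper quartiles of intensity were 348 on DE 3, 537 and 626 on DE 1 and 2 and 316 to 438 elsewhere. RNA of endothelial or blood cells is a candidate, with Emcn at 13.23 and Hbb-bh1 at 8.29 on DE 3. Of 14 tested list members, Kdr (4.79), Gata1 (5.44) and Runx1 (7.01) were not 2-fold higher. Another list holds 0 of the 14. A gate on Sox17 would not remove endothelial cells, which express it, and the gate is not stated. Fewer endoderm cells stay open as a cause of the lower Nodal and mesendoderm genes: among genes detected on DE 1 and 2, 23 such genes had a median change of -1.86 and 36 other genes of the endoderm lists of -0.386, a difference of 1.48 (permutation p = 2e-04, 10000 permutations). That set holds extraembryonic and matrix genes, whose list lay 0.91 higher on DE 3. For the 14 other definitive endoderm genes alone the difference was 0.925 (permutation p = 0.0632), below the bound of 1 log2 that would argue against it. An earlier or later stage also stays open, untested.

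The Y-linked gene Eif2s3y is lower on ES 1 and 2 than on ES 3 by 3.40, and Uty by 1.44. A slide difference is argued against, since the DE and AFE arrays of slide 1 lie at least 1.93 above ES 1 and 2 for Eif2s3y. For Uty the gap is smaller, with DE 3 at 5.72 and ES 2 at 5.10. More feeders on ES 3 are argued against as the whole cause: the fibroblast list rises by a median of 1.3, 0 of 21 members reach the change of Eif2s3y, and ES 3, at 11.18, lies within the range of the DE and AFE arrays. Against ES 3 alone, X-linked less autosomal genes of ES 1 and 2 lay at -0.183 (95% range over genes -0.238 to -0.116). A second active X would raise them. Loss of the Y or another line stays open, untested. No group of the design applies.

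Splits of the arrays were counted for each comparison. For DE against ES, AFE against DE and AFE against ES the 10 splits are too few for a share under 0.05; the real split gave 4503, 2358 and 4319 genes and the highest other 0, 15 and 0, so that 1 split of 10 reached the real count each time. For the F-test, 1 of 100 splits drawn from 280, the real one, reached 5713 genes and the highest other gave 2879, a share under 0.05 that excludes chance only for independent arrays. That they are independent is not established.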

How the results depend on the processing

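The tests on the authors' values without the unmatched column, on replicates 1 and 2 averaged and without both DE 3 and ES 3 were chosen after the data were seen; the other alternatives were fixed before. List medians are given where the sign changed, except some uncalled lists, and for pluripotency, definitive endoderm and anterior foregut also where a call changed. Among all 117 list results, calls were lost, and gained, without a change of sign in 71 and 0 with camera and an estimated correlation, 39 and 1 with replicates averaged, 35 and 1 with the authors' values as labelled, 33 and 3 with camera and its preset correlation, 15 and 5 with only the 6 arrays compared, 3 and 14 without DE 3 and 4 and 17 without DE 3 and ES 3. The authors' values differ in background, normalization and the array under 2 ES labels at once, and 1 version also drops an array. In that version, without the unmatched ES column, 15 of 15 counts stayed within 1.5 times and 0 of 454 results for named genes changed sign; leaving out DE 3 and ES 3 removes 2 arrays. The background fitted without detection p-values also has an offset of 50 in place of 16, and camera, unlike fry, compares a list with the other genes. Each probe by itself counts probes, not genes. The intensity trend came with robust moderation, the rest changed 1 choice each, and no cause was tested here. Of 454 named gene results, 154 kept call and sign in every alternative run and 3 changed sign in at least 1. Of 117 list results 17 and 10 did, the 10 leaving out some uncalled lists. Of 15 counts, 0 stayed within 1.5 times in all alternatives. With the replicate block, 2161 genes were higher and 2127 lower in DE against ES, 1126 and 971 in AFE against DE, and 2231 and 1930 in AFE against ES. Where leaving out 1 array leaves 2 in a group, the spread is pooled over groups.

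With the authors' processed values with columns as labelled, genes numbered 361 higher, 306 lower, 336 2-fold higher, 261 2-fold lower in DE against ES, 392 higher, 491 lower, 320 2-fold higher, 430 2-fold lower in AFE against DE, 699 higher, 636 lower, 622 2-fold higher, 519 2-fold lower in AFE against ES, 1817 among the 3 groups, 148 higher in both DE and AFE than ES, 139 lower in both DE and AFE than ES. There, list medians were pluripotency -3.87, definitive endoderm 2.84, retinoic acid 0.37 in DE against ES, definitive endoderm -2.46, posterior gut -0.10, paraxial and axial mesoderm -0.0781 in AFE against DE, pluripotency -4.15, definitive endoderm 0.26, posterior gut -0.13 in AFE against ES. There, the log2 change had the other sign for Crabp1 in DE against ES 0.28, Lgr5 in AFE against ES -0.0809, Sox2 in AFE against ES 0.47. With a test against a fold of 1.5 (treat), genes numbered 896 higher, 959 lower, 896 2-fold higher in DE against ES, 260 higher, 305 lower, 260 2-fold higher, 305 2-fold lower in AFE against DE, 909 higher, 813 lower, 909 2-fold higher, 813 2-fold lower in AFE against ES. With replicates 1 and 2 averaged to 1 sample, genes numbered 946 higher, 1053 lower, 925 2-fold higher in DE against ES, 191 higher, 196 lower, 191 2-fold higher, 196 2-fold lower in AFE against DE, 1094 higher, 950 lower in AFE against ES, 2370 among the 3 groups, 507 higher in both DE and AFE than ES, 663 lower in both DE and AFE than ES. There, list medians were definitive endoderm -2.15, posterior gut -0.42, neural 0.0163 in AFE against DE, definitive endoderm 1.73 in AFE against ES. With each probe by itself, probes numbered 3412 lower in DE against ES, 3137 lower, 1980 2-fold lower in AFE against ES. With no background correction, genes numbered 906 2-fold higher, 879 2-fold lower in DE against ES, 377 2-fold higher, 447 2-fold lower in AFE against DE, 863 2-fold higher, 762 2-fold lower in AFE against ES. There, list medians were posterior gut -0.096 in AFE against DE. With median scaling, genes numbered 652 higher, 423 2-fold higher in AFE against DE. There, list medians were posterior gut -0.20, paraxial and axial mesoderm -0.18, BMP targets -0.16 in AFE against DE. With DE 3 and ES 3 left out, genes numbered 1590 lower in AFE against DE. There, list medians were anterior foregut 0.0604 in DE against ES, posterior gut -0.17, neural 0.00204, BMP targets -0.045 in AFE against DE. With the background fitted without detection p-values and an offset of 50, genes numbered 457 2-fold higher in AFE against DE, 988 2-fold higher in AFE against ES. There, list medians were posterior gut -0.0832 in AFE against DE. With camera with an estimated correlation, of the pluripotency, definitive endoderm and anterior foregut lists those no longer called, at the same medians, were pluripotency -5.38, definitive endoderm 3.99 in DE against ES, definitive endoderm -2.35, anterior foregut 2.44 in AFE against DE, pluripotency -5.70, definitive endoderm 1.64, anterior foregut 2.65 in AFE against ES. With the stricter filter, list medians were anterior foregut 1.69, retinoic acid 1.29 in DE against ES, paraxial and axial mesoderm -0.39, hedgehog -0.14, imprinted 0.13 in AFE against DE. With only the 6 arrays compared, of the pluripotency, definitive endoderm and anterior foregut lists those no longer called, at the same medians, were definitive endoderm -2.35 in AFE against DE. With cyclic loess, list medians were posterior gut -0.0309, neural 0.0804, oxidative phosphorylation -0.0276 in AFE against DE. With the mean of a gene's probes, list medians were posterior gut -0.0166 in AFE against DE. With the authors' values without the unmatched ES column, list medians were posterior gut -0.10, paraxial and axial mesoderm -0.0781 in AFE against DE, mitosis -0.14 in AFE against ES. With no filter, list medians were paraxial and axial mesoderm -0.0166 in AFE against DE. On leaving out each array in turn, values ran from 742 to 1747 genes higher in AFE against DE, 679 to 1488 genes lower in AFE against DE, 0.0873 to 0.23 for anterior foregut in DE against ES, -0.69 to 0.0407 for pluripotency in AFE against DE, -0.50 to 0.0926 for posterior gut in AFE against DE, -0.19 to 0.00588 for neural in AFE against DE, -0.32 to 0.35 for paraxial and axial mesoderm in AFE against DE, -0.0849 to 0.16 for BMP targets in AFE against DE, -0.13 to 0.19 for imprinted in AFE against DE.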

Other observations

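The tests of single arrays against the others of their group, and the genes named here, were chosen after the results were seen.

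Some genes of ES cells differed within groups. Dppa4, a gene of pluripotent cells, stood at 5.40, 5.44 and 9.92 on DE 1, 2 and 3, highest on the array with the endothelial genes. Dnmt3l, a cofactor of DNA methylation, stood at 5.30, 8.64 and 5.92 on AFE 1, 2 and 3, highest on the array with the highest Nanog. Emb, a gene of the cell surface, stood at 5.91, 6.14 and 12.53 on ES 1, 2 and 3, against means of 14.71 in DE and 13.87 in AFE. In DE 3 Tek, a receptor of endothelial cells, stood at 11.46 against 6.31 and 6.07 in DE 1 and 2, and Lmo2, a factor of blood precursors, at 11.48 against 7.87 and 7.85.

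AFE arrays differed in some genes known from muscle or blood, and the source was not tested. Actc1, an actin of heart muscle, stood at 8.03, 8.43 and 11.79 on AFE 1, 2 and 3, and Ankrd1, a stress gene of muscle, at 5.78, 6.91 and 10.58. The embryonic globin Hbb-y stood at 10.92, 8.57 and 4.49. Against the other arrays of the group, AFE 3 had 548 genes at least 2-fold higher and 425 lower. The replicate numbers did not pair the groups, with correlations across genes, which are not independent replicates, from -0.143 to 0.0748.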
